A study of Homo sapiens with 8 samples.

How the data were processed

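MicroRNA levels were measured by RT-PCR on TaqMan Array Human MicroRNA cards, version 3.0, in RNA from exosomes, the small vesicles that cells release into their medium. The exosomes came from cultures of primary human melanocytes, the pigment cells of the skin. Per the labels, quiescent cells were irradiated with solar UVA and UVB light on day 1 and a second time 24 h later, and exosomal RNA was extracted by 64 h after irradiation. The series holds 8 samples. Each card, A or B, carries a different set of assays and was run on 1 unirradiated sample (0 mJ) and 3 irradiated samples (25 mJ, the area not being stated). The irradiated samples are replicates a, b and c on card A and d, e and f on card B, and nothing in the labels pairs a letter of one card with a letter of the other. The series calls them experimental replicates without saying whether they came from separate cultures or donors, so p-values measure only the spread between these samples, which can be technical.

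The authors deposited 1 ratio per assay and irradiated sample, the relative quantity (RQ) of the comparative cycle method. Per the file headers the ratio is an RQ value and U6, a small nuclear RNA, is named beside the card, which was read as the RNA used for normalization. The calibrator is not named. It was taken to be the unirradiated sample of the same card, which has no column of its own, so an RQ of 1 stands for the unirradiated level. All directions given rest on that reading. The software, the treatment of undetermined cycles and the rule by which assays entered the tables are not given in the sources used here. Cycle values and the control small RNAs were not analysed here, so the signal depth behind each ratio is unknown and no counting interval is given. The tables list 112 assays on card A and 59 on card B, under the names of the card's design. No genome build is named, so no coordinates are printed. The authors' column of average ratios lay within 0.001 of the mean of the 3 deposited ratios for all 96 averages of card A and for 44 of the 45 of card B. The remaining card B average, for miR-18a*, was given although a replicate was blank, and equals the value of replicate f. No average was given for 1 complete assay of card A (miR-146b) and 2 of card B (miR-320B and miR-590-3P).

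From these ratios, commas inside numbers were removed and log2(RQ) was taken without a pseudocount. Assays with a value in all 3 replicates were tested, 97 on card A and 46 on card B. The mean log2(RQ) of the 3 replicates was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment within the card and a threshold of 0.05. Cards were tested separately because each was normalized on its own. This test leaves out the spread of the unirradiated sample, of which there is 1 per card. In a second fit the unirradiated sample was therefore entered as a sample with log2(RQ) of 0, assumed to vary like the irradiated ones, and its counts stand beside the others. Whether the unirradiated sample was a pool of controls is not known, and a pool need not vary like a single sample. Even with an unirradiated sample free of error, an exact two-sided sign test of 3 replicates cannot give a p below 0.25. Folds in the text are geometric means of the 3 RQ values, and SDs are of log2(RQ) with n = 3.

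Both fits were tested on 100 simulated cards per comparison, with 97 assays for card A and 46 for card B and with spreads drawn from the fitted prior. About as many assays were changed as unchanged, by 4- or 16-fold, up or down with equal odds. Noise was independent and no shift was common to all assays. The shares below depend on these settings and do not carry over to the calls made here. Where the simulated control had no error, the test against 0 recovered 84.6% of 4-fold changes on card A and 58.0% on card B, and 3.05% and 3.77% of its calls were false. Where the control varied like the other samples, 19.7% of the calls on card A and 21.4% on card B were false, against 3.19% and 3.80% when the control was entered as a sample. That second fit recovered 14.3% of 4-fold and 70.6% of 16-fold changes on card A, and 4.55% and 30.4% on card B.

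Before the data were examined, 18 lists of microRNAs were fixed (senescence-associated, p53-responsive, UV and DNA damage response, inflammation-linked, melanocyte lineage and pigmentation, the let-7, miR-200, miR-15/16 and miR-29 and miR-30 families, the miR-17 cluster with its paralogues, the Xq27, 14q32 and 19q13 clusters, markers of keratinocytes, fibroblasts, blood cells and liver or serum, and control assays). Members were matched by the assay's name with or without its arm suffix, and star forms (the minor strand) were not counted. Lists with at least 3 measured members, 10 on card A and 1 on card B, were tested with limma's camera, which sets a list against the other assays of the card (preset correlation 0.01). They were also tested with fry, which asks whether a list's members lie on 1 side of 0. On simulated cards of 97 assays with independent noise, camera and fry each called a list of 10 assays shifted by 2 log2 units in 100% of cards at an unadjusted p under 0.05. They called an unshifted list in 2% and 7%. These simulated cards had no shift common to all assays and no error of the control. Their shares therefore do not carry over to the list calls made here, least of all to those of fry against 0.

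The named assays follow a rule fixed at the same time. It takes the 10 highest and 10 lowest called assays per card with all replicates on 1 side of 1, and up to 5 lower assays as values where fewer than 10 were called lower. It adds up to 4 members per list with the largest mean change and a short fixed set (miR-34a, miR-146a, miR-21, miR-211, miR-204, let-7a, miR-203, miR-205, miR-451 and control assays). Of that set miR-34a, miR-146a, miR-21 and miR-211 were listed, and the others were not analysed here. Alternatives were median centring of each sample, at least 2 of 3 values, a limit on extreme ratios (1000 and 0.001), a pseudocount of 0.1, a robust variance, an added 2-fold minimum, adjustment over both cards, and leaving out each replicate. Others, chosen after the data were seen, are named in the closing section. Figures were drawn with matplotlib 3.10.9.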

Results

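The series compared microRNAs in exosomes of quiescent melanocytes exposed to solar ultraviolet light (25 mJ, given on day 1 and again 24 h later) with those of unirradiated cells, and its title links these microRNAs to premature senescence. Card A listed 112 assays, of which 97 had a ratio in each of replicates a, b and c. Card B listed 59, of which 46 had a ratio in each of replicates d, e and f. Blank cells were most frequent in replicate b (12 of card A) and replicate e (10 of card B), against 1 to 3 in each of the others. The cycle values behind the ratios were not analysed here, so the depth of each sample is unknown. Ratios ran from 0.001 to 233 on card A and from 0.002 to 2530 on card B. Across assays, which are not independent replicates, log2 ratios of 2 replicates correlated with r = 0.57 to 0.75 on card A and 0.84 to 0.92 on card B.

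The first comparison asked which microRNAs of card A, which holds most of the well-known human microRNAs, differed in exosomes after irradiation. Most listed assays were above the unirradiated sample. Of the 97 tested, 47 were higher and 5 were lower (limma, adjusted p under the threshold), and the median assay stood at 2.31-fold. In 81 assays all 3 replicates lay above 1 and in 8 all lay below, where unchanged levels would put 50% of assays wholly on either side if the shared unirradiated sample varied like the others, and 25% if it had no error. Both percentages assume assays listed without regard to their values, and the listing rule is not known. Among the higher microRNAs were miR-34a, a known p53 target linked to cell-cycle arrest and senescence, and miR-21, a widely expressed growth- and stress-linked microRNA. miR-34a rose 5.16-fold (log2 2.37 ± 0.20, SD, n = 3, adjusted p = 0.00869) and miR-21 rose 5.02-fold (log2 2.33 ± 0.05, adjusted p = 0.00869). The miR-34a call was lost without replicate b (log2 2.27, adjusted p = 0.061) and the miR-21 call without a (log2 2.35) or b (log2 2.31), although these means barely moved. Neither passed after centring (adjusted p = 0.108 and 0.113). With the unirradiated sample entered as a sample of its own, only miR-642 kept its call on card A (adjusted p = 0.0133), and 15 assays had an unadjusted p under 0.05. With each sample centred on its median, 5 assays were higher and 9 lower, and without replicate b 4 were higher and 1 lower.

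The 10 highest called assays of card A spanned 5.17-fold to 128-fold. miR-642 had the largest ratio, 128-fold (SD of log2 0.80, n = 3, adjusted p = 1.35e-04), with 115, 78.3 and 233 in replicates a, b and c. miR-339-3p followed at 27.8-fold (log2 4.80 ± 1.31), miR-576-3p at 19.8-fold (4.31 ± 0.59) and miR-376a, of the imprinted 14q32 cluster, at 17.4-fold (4.12 ± 1.16). miR-101, a repressor of the histone methyltransferase EZH2, rose 7.79-fold (2.96 ± 0.87). The next were miR-590-5p (7.18-fold), miR-483-5p (6.29-fold, from an intron of IGF2), miR-301b (6.22-fold), miR-24 (5.33-fold) and miR-28 (5.17-fold). The miR-590-5p ratio rested on replicates a and c, at 14.6 and 18.3, against 1.38 in b. miR-642, miR-339-3p, miR-576-3p, miR-376a and miR-101 were also called higher after centring. The other 5 named here were then above the card's median too (centred log2 1.18 to 1.65) but were not called. Leaving out each replicate in turn, miR-642, miR-576-3p, miR-376a and the lower miR-369-3p kept their calls each time, and 27 of the 52 calls were kept in no such fit. These limma fits differed in more than the means, and in the fit without a an assay's own spread carried no weight. miR-642 had its highest mean without b (log2 7.36), yet also its highest adjusted p (0.0149, against 4.0e-10 without a).

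The 5 lower assays of card A differed widely between replicates. miR-142-3p, a microRNA of blood cells, had the lowest mean ratio, 0.00964 (log2 -6.70 ± 4.06, adjusted p = 0.0111), with 0.001, 0.004 and 0.224 in a, b and c. miR-369-3p of the 14q32 cluster stood at 0.0175 (-5.84 ± 3.19), let-7d at 0.0352 (-4.83 ± 3.88), miR-29b, which targets collagen and other matrix transcripts, at 0.0793 (-3.66 ± 2.10) and miR-519e of the primate-specific 19q13 cluster at 0.224 (-2.16 ± 1.93). All 5 stayed lower after centring. Without replicate b the calls of miR-142-3p, let-7d (then at log2 -2.76), miR-29b and miR-519e were lost, and the miR-519e call was lost without a or c as well. miR-454 (0.539), miR-181a (0.595) and miR-628-5p (0.638) were below 1 in every replicate without passing the test, and these 3 and miR-515-3p were called lower after centring.

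**Figure D1:**
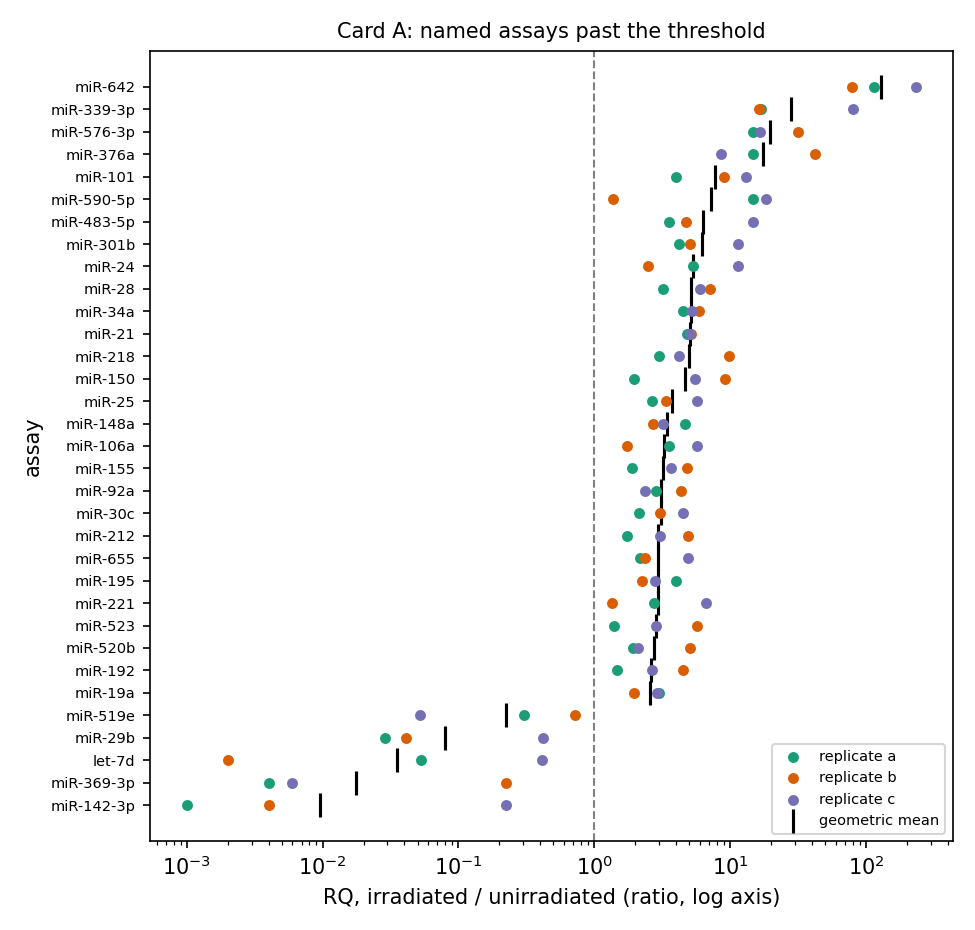
RQ of each irradiated replicate (points, replicates a, b and c) and their geometric mean (black ticks) on a log axis, for the 33 named card A assays past the threshold; the dashed line at 1 is the unirradiated sample. The replicates of miR-34a and miR-21 lie close together near 5-fold, while those of the 5 lower assays, such as miR-142-3p at 0.001 to 0.224, are far apart.

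By list, the UV and DNA damage response list had 8 of 9 measured members higher on card A, and the same number when adjusted over the list alone. They were miR-101, miR-24, miR-34a, miR-21, miR-155, miR-27a, miR-192 and miR-365, while miR-16 was at 1.01-fold. Of these miR-27a and miR-365 lay outside the naming rule and were named after their values were seen. miR-155, an inflammation-linked microRNA, stood at 3.22-fold (log2 1.69 ± 0.69) and the p53-responsive miR-192 at 2.59-fold (1.37 ± 0.82). The senescence-associated list had 6 of 13 members higher, miR-29b lower and 6 not called (7 called when adjusted over the list alone). Its higher members included miR-376a, miR-24, miR-34a and miR-21. miR-146a and miR-146b, which restrain NF-kB signalling, were at 1.86-fold (log2 0.89 ± 0.28, adjusted p = 0.0877) and at log2 1.00 ± 0.50 (adjusted p = 0.0771). The p53-responsive list had 2 of 3 members higher (miR-34a and miR-192; 2 adjusted over the list alone). The inflammation-linked list had 3 of 6 higher (miR-21, miR-155 and miR-212 at 2.96-fold; 3 adjusted over the list alone).

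The miR-17 cluster and its paralogues, proliferation-linked microRNAs, had 7 of 10 members higher and none lower (8 called when adjusted over the list alone). miR-25 was at 3.70-fold (log2 1.89 ± 0.56), miR-106a at 3.28-fold (1.71 ± 0.86), miR-92a at 3.09-fold (1.63 ± 0.45) and miR-19a at 2.55-fold (1.35 ± 0.34). Members of these clusters are close in sequence, and whether the assays cross-detect them was not examined. Of the melanocyte lineage and pigmentation list, 3 of 7 were higher, namely miR-25, miR-148a (3.42-fold) and miR-221 (2.92-fold), and 2 when adjusted over the list alone. miR-211, which lies in an intron of the melanocyte gene TRPM1, was at 2.07-fold (log2 1.05 ± 0.46, adjusted p = 0.066), and miR-193b was at 2.39-fold (1.26 ± 1.31, adjusted p = 0.0866). The Xq27 cluster had 0 of 2 called by limma (miR-888 at 3.07-fold and miR-509-5p at 2.31-fold, both above 1 in all replicates).

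Some smaller families and clusters went both ways. In the 14q32 cluster miR-376a and miR-655 (2.92-fold) were higher, miR-369-3p lower and miR-494 (1.64-fold) not called, so 3 of 4 were called, and 3 when adjusted over the list alone. In the 19q13 cluster miR-523 (2.84-fold) and miR-520b (2.74-fold) were higher and miR-519e lower among 6, and miR-515-3p at 0.427 was not called (3 called when adjusted over the list alone). Of the miR-29 and miR-30 families, miR-30c was higher (3.08-fold) and miR-29b lower among 5, with miR-29c at 2.22-fold and miR-29a at 1.87-fold not called (2 when adjusted over the list alone). In the miR-15/16 family miR-195 was higher (2.92-fold) and miR-16 was not called. let-7d was the only measured let-7 member.

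Among markers of other cell types on card A, the fibroblast-linked miR-218 was at 4.98-fold (log2 2.31 ± 0.87, adjusted p = 0.0125). The blood cell markers split, with miR-150 higher at 4.63-fold, miR-142-3p lower and miR-223 at 1.97-fold not called (2 called when adjusted over the list alone). miR-192, also enriched in liver, is named above. Keratinocyte markers and the miR-200 family had 0 listed assays and were not analysed here.

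None of the 10 lists tested on card A stood apart from the other assays of the card by camera, which made 0 calls at adjusted p under the threshold with the preset or an estimated correlation. The lowest camera value was that of the 19q13 cluster, in the lower direction (adjusted p = 0.283, and 0.821 with an estimated correlation), and it was called only without replicate b (adjusted p = 0.0476). Against the unirradiated level itself, fry called 5 lists, all higher. These were the senescence-associated, p53-responsive, UV and DNA damage response and miR-17 cluster lists (adjusted p = 0.0249 each) and the inflammation-linked list (0.0273). Some of these lists share members, so their calls are not separate results. All measured p53-responsive members (miR-16, miR-192 and miR-34a) are also in the UV list. miR-21 is in the UV, senescence-associated and inflammation-linked lists. The melanocyte list was not called (adjusted p = 0.0633), nor were the 14q32 (0.0799), miR-29 and miR-30 (0.199), blood cell (0.552) and 19q13 (0.609) lists. For those last 4 camera pointed lower and fry higher. Their medians were above 0, and of their means that of the blood cell list alone was below (log2 -1.17). With the unirradiated sample entered as a sample, fry called 0 lists, with adjusted p = 0.0951 for the first 4 and 0.103 for the inflammation-linked list. After centring, fry called the UV and DNA damage response list alone (adjusted p = 0.0035), and the senescence-associated list then pointed lower without passing (0.718). The members called higher after centring numbered 1 each in the UV, senescence-associated and 14q32 lists (miR-101 in the first, miR-376a in the others) and 0 in the remaining lists of card A.

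The second comparison asked the same of card B, which holds rarer microRNAs and many star forms. Of 46 assays tested, 21 were higher and 3 lower, with a median of 2.85-fold. In 31 assays all replicates lay above 1 and in 11 all lay below. Of the p53-linked miR-34 family, 2 assays were higher. The minor strand miR-34a* stood at 28.6-fold (log2 4.84 ± 0.73, adjusted p = 3.08e-04) and miR-34b at 9.06-fold (3.18 ± 1.38, adjusted p = 0.00608). With the unirradiated sample entered as a sample, 9 assays were higher and 2 lower, and miR-34a* kept its call (adjusted p = 0.0201) while miR-34b did not (0.146). After centring 11 were higher and 11 lower. In that limma fit the adjusted p followed the size of the centred mean alone, so an assay's own spread carried no weight. miR-650 (SD 3.21, centred log2 -6.99) had an adjusted p of 7.1e-14, and miR-769-5p (SD 0.65, centred log2 6.92) had 9.2e-14. Without replicate d 12 were higher and 3 lower, and the miR-34b call was lost without d, without f and after centring (adjusted p = 0.0971).

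The largest ratios of the study were on card B. miR-320B stood at 923-fold (log2 9.85 ± 0.45, adjusted p = 1.52e-05), with 653, 1012 and 1190 in d, e and f. On card A, which was normalized separately, the assay named miR-320 was at 2.22-fold. It lay outside the naming rule, and the difference between these assays was not tested. miR-22*, the minor strand of a senescence-linked microRNA, was at 559-fold (9.13 ± 1.15), miR-769-5p at 395-fold (8.62 ± 0.65), miR-1285, which targets p53 transcripts, at 334-fold (8.38 ± 1.58), miR-1300 at 172-fold (7.42 ± 2.28) and miR-191* at 138-fold (7.10 ± 0.30). Of these miR-1300 varied most, with 28.8, 588 and 299 in d, e and f. miR-645 followed at 40.7-fold (5.35 ± 0.68), then miR-34a*, miR-30a-5p at log2 4.46 ± 0.86 and miR-338-5P at 13.2-fold (3.72 ± 0.95). With the unirradiated sample entered as a sample, 9 of these 10 card B assays kept their calls, and miR-338-5P did not (adjusted p = 0.0628). The level of these assays in the unirradiated sample is not known, and 9 of the 15 assays with a mean ratio above 50 on this card had a blank replicate (7 of them e), against 4 of the other 44.

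**Figure D2:**
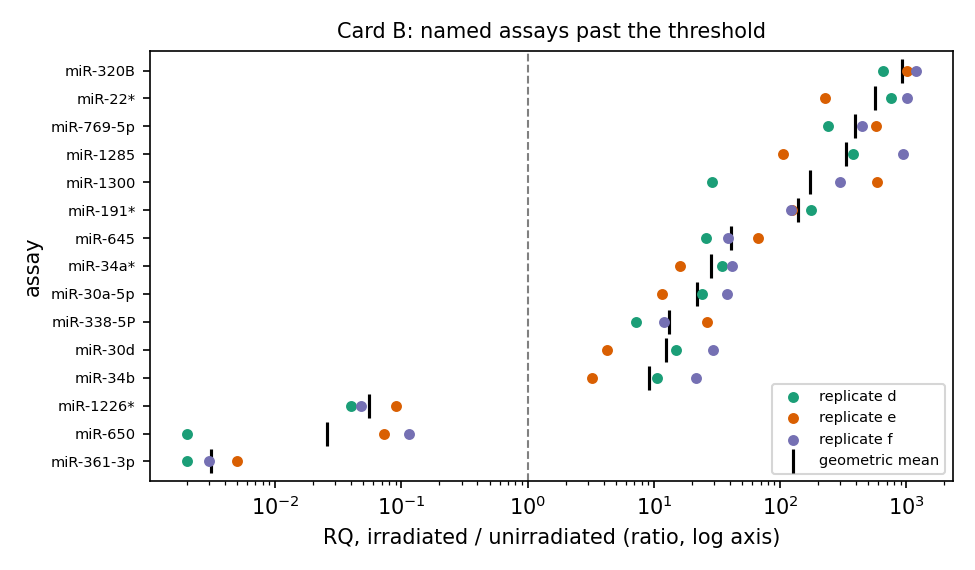
RQ of each irradiated replicate (points, replicates d, e and f) and their geometric mean (black ticks) on a log axis, for the 15 named card B assays past the threshold; the dashed line at 1 is the unirradiated sample. The points of miR-320B lie between 653 and 1190, and those of miR-361-3p between 0.002 and 0.005.

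The 3 lower assays of card B were miR-361-3p at 0.00311 (log2 -8.33 ± 0.66, adjusted p = 1.81e-05), miR-650 at 0.0257 (-5.28 ± 3.21, adjusted p = 0.00606) and miR-1226* at 0.0559 (-4.16 ± 0.62, adjusted p = 5.85e-04). The miR-650 ratio was far lower in d, at 0.002, than in e and f, at 0.073 and 0.116. miR-361-3p and miR-1226* kept their calls with the unirradiated sample entered as a sample (adjusted p = 0.00191 and 0.0319), and miR-650 did not (0.146). miR-628-3p (0.159), miR-590-3P (0.191), miR-625* (0.329), miR-151-5P (0.520) and miR-222* (0.596) were below 1 in all replicates without passing. All 5 were called lower after centring, in the fit that gave no weight to their own spread. In the first 3 of these the low mean rested on replicate e, at 0.013, 0.016 and 0.056. Of the miR-29 and miR-30 families on card B, miR-30a-5p and miR-30d (12.4-fold, log2 3.63 ± 1.41) were higher, and miR-30a-3p (2.73-fold) and miR-30e-3p (2.70-fold) were not called (2 called when adjusted over the list alone). That list did not stand apart from the card by camera (adjusted p = 0.309, and 0.643 with an estimated correlation). Against the unirradiated level fry gave adjusted p = 0.0404, a call lost with the unirradiated sample entered as a sample (0.137) and after centring (0.0838). miR-520c-3p, of the 19q13 cluster, was at 0.708 and not called, except as lower after centring. miR-34b was the single complete card B member of the senescence-associated, p53-responsive and UV lists, and the remaining lists had none there.

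A group of 6 assays was singled out after the values were seen, because most of its members differed widely between irradiated replicates. Some other assays varied more, such as miR-627 (SD of log2 4.92, RQ 0.009 to 5.79) and miR-142-3p (SD 4.06). The targets of miR-886-3p and miR-886-5p are now assigned to the vault-like RNA nc886, and those of miR-1274A, miR-1274B, miR-720 and miR-1260 to tRNA fragments. miR-1274B had RQ 0.241, 2.78 and 10.9 in d, e and f, miR-720 had 0.431, 2.62 and 9.22, and miR-886-3p had 0.156, 1.01 and 4.47 in a, b and c. The median span between the lowest and highest replicate was 4.63 log2 units for the 6 assays and 1.32 for the others, with miR-1260 the narrowest of the 6 at 2.20. None of the 6 was called different from the unirradiated sample by limma (adjusted p from 0.0701 for miR-1260 to 0.93 for miR-1274A).

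**Figure D3:**
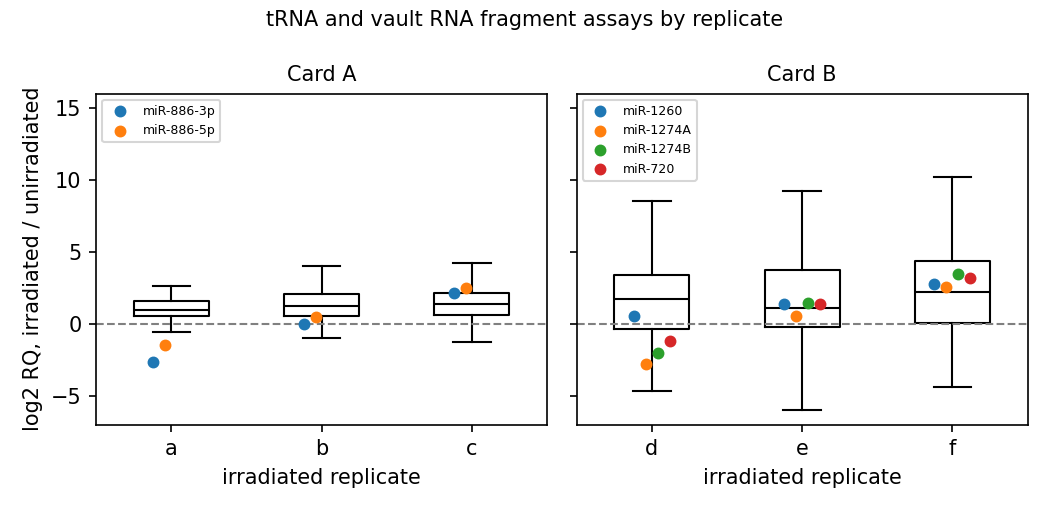
log2 RQ by irradiated replicate on card A (left) and card B (right) for assays of vault RNA and tRNA fragments (coloured points), over box plots of all other tested assays (box, quartiles; line, median; whiskers, range without far outliers, which are not drawn); the dashed line is the unirradiated sample. On card B all 4 are lowest in replicate d and highest in f.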

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

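Tests of explanations in this part were all chosen after the values were seen. Blank cells kept 28 assays out of the comparisons, and 10 of the 26 with 2 values had both above 10. The geometric means of the 2 values were 792 for miR-1303, 534 for miR-605, 209 for miR-126*, 170 for miR-10b*, 168 for miR-616, 106 for miR-9*, 91.5 for miR-26b*, 81.1 for miR-18a* and 14.6 for miR-31* on card B, and 16.6 for miR-324-3p on card A. They are singled out because a signal well above the unirradiated level stands in data that the main comparisons did not use. A fit of all assays with at least 2 of 3 values did use them and called all 10 higher. The values of miR-605, which is linked to p53, were 549 and 520, those of miR-9* 108 and 105, and those of miR-1303 248 and 2530. Each has 1 blank replicate.

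Ratios above 50 were found in 15 assays of card B and 1 of card A. On card B no mean ratio lay between 40.7 and 81.1. A candidate explanation is an unirradiated level at or near the detection limit, where a small signal in the calibrator gives a very large ratio. The values of the unirradiated sample were not analysed here, so this stays open, as does a gain of these microRNAs after irradiation. In the irradiated replicates 9 of the 15 assays had a blank against 4 of the other 44 (Fisher's exact test, two-sided, p = 1.78e-04). Of the 9, 7 were blank in replicate e, which had 10 blanks in all, and blanks of irradiated samples do not measure the unirradiated level.

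A technical explanation of the predominance of ratios above 1 could be examined, and another of the agreement of replicates on 1 side of 1. A difference common to all assays, such as less U6 in the irradiated samples, would shift every ratio alike. After centring, 10.6% of the higher calls of card A (exact 95% interval 3.55 to 23.1%) and 52.4% of card B (29.8 to 74.3%) were still higher past the threshold, so a common shift cannot be told apart from a like change of many microRNAs for the calls that were lost, because centring removes both alike. The card B share comes from the centred fit in which an assay's own spread carried no weight. Both intervals treat called assays as independent, although the assays of a card share its samples and calibrator. A choice of listed assays by like direction would leave few assays with replicates on both sides of 1. It would keep assays below 1 as readily as those above, so by itself, with no common shift, it would not give the predominance of ratios above 1. Card A had 8 such assays against a median of 15 in 10000 simulated cards with the same means and the card's median spread (share with as few 0.0136, and 0.0098 with each assay's own SD), as such a choice would give. Card B had 4 against 7 (0.0932, and 0.044 with each assay's own SD), which leaves it open there. Together with a common upward shift, such a choice could add to the predominance. A listing rule that favoured ratios above 1 was not tested. On card A 12 values lay from 1 to 1.2 and 1 from 1/1.2 to 1, while on card B these numbers were 1 and 5. Irradiation, the difference the design names, stays open beside these explanations.

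The 6 tRNA and vault RNA assays, chosen for their wide differences, spanned a median of 4.42 log2 units between replicates on card A and 4.89 on card B. The replicate medians of all other tested assays differed by at most 0.47 on card A and 1.08 on card B (upper limits of the 95% bootstrap intervals 0.69 and 2.03), below these median spans. A span also holds an assay's own noise, and the median span of the other assays, 1.32 over both cards, was above both differences too. As the 6 were picked for wide spans, the comparison cannot decide on a normalization difference of whole replicates. Independent noise near the detection limit stays open. The 4 card B assays ordered the replicates alike, and noise gives 1 shared order, whichever it is, with an exact probability of 0.00463 in a group fixed beforehand, but this group was picked with its values in view. No biological explanation was tested, since all replicates had the same dose.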

How the results depend on the processing

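Calls on card A fell from 52 to 1 with the unirradiated sample entered as a sample, to 14 (5 higher, 9 lower) with each sample centred on its median, and to 4 (1 higher, 3 lower) with both. They ranged from 5 (without replicate b) to 26 (without c) when replicates were left out, with 17 without a. The median shift without b was log2 1.18, against 1.21 in the main fit. In the card A limma fits without a and with the pseudocount, the adjusted p of named assays followed the size of the mean alone. Without a, let-7d (log2 -5.12, RQ 0.002 and 0.413) and miR-339-3p (log2 5.16) both had 3.7e-06. Counts of calls thus also depend on how each fit weighed spread. On card B the 24 calls fell to 11 (9 higher, 2 lower) with the unirradiated sample entered as a sample and to 11 (6 higher, 5 lower, 2 of them new) with centring added, were 22 (11 higher, 11 lower) after centring, and ranged from 15 (without d) to 27 (without e). Leaving out cells stored as short decimals, which also admitted assays with 2 values, gave 18 calls (18 higher, 0 lower, so that no lower call was kept) among 82 assays on card A and 32 among 51 on card B, against 63 among 112 and 34 among 57 for at least 2 values alone. Of the 52 and 24 calls, 16 and 21 were kept there. That alternative, the combined one, the star forms and 2 of the fry settings were chosen after seeing the data. Under at least 2 of 3 values, the limit on extreme ratios (which removed no card A assay, so it tests nothing there), the pseudocount, the robust variance, the 2-fold minimum and adjustment over both cards, the counts stayed within 1.5 times. The pseudocount kept the calls of the lowest assays but shrank their log2 ratios, from -6.70 to -2.87 for miR-142-3p, from -4.83 to -2.46 for let-7d and from -8.33 to -3.41 for miR-361-3p, as it does by construction. Centring moved the median shift to 0.016 on card A and -0.20 on card B by construction. Lists called numbered 0 with camera on both cards, 5 on card A and 1 on card B with fry, 1 on card A with fry after centring, and 0 to 1 on card A when replicates were left out. Of the called named assays, 32 of 33 on card A and 4 of 15 on card B lost their calls with the unirradiated sample entered as a sample, and 23 and 1 with centring, under which 4 and 6 uncalled ones were called lower. Under centring the mean log2 ratios of uncalled named assays fell below 0 for miR-29c (-0.041), miR-211 (-0.14), miR-146b (-0.19), miR-223 (-0.21), miR-29a (-0.29), miR-146a (-0.30), miR-494 (-0.48), miR-16 (-1.18), miR-30a-3p (-0.26) and miR-30e-3p (-0.28). Assays outside the named set did so too, among them miR-320 (-0.042) and miR-574-3p (-0.035), which the main fit called higher. miR-16, at 0.01, went to -0.27 without replicate a and -0.20 without c, and was 0.50 without b. The cause of each change was not tested, except that entering the control widens the standard error. No paired analysis was possible because each card has 1 unirradiated sample and its replicate letters are its own. Other splits of the samples could not be counted with 1 control. The unknown cycle values limit all low and high ratios.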

Other observations

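For 9 precursors, tested assays named for both strands could be set side by side, most across cards that were normalized separately. In 4 of them the strands lay on opposite sides of 1. These were miR-590 (5p higher at 7.18-fold, 3P at 0.191 and not called), miR-454 (0.539, not called, and star form higher at 2.98-fold), miR-222 (1.56 and 0.596 for the star form) and miR-151 (3p at 1.42 and 5P at 0.520), with neither strand called in the last 2. After centring the miR-590-5p and miR-454* calls were lost, miR-454* turned to log2 -0.13, and the strands on opposite sides of the median were those of 4 pairs (miR-590, miR-191, miR-28 and miR-30a). Of the others, miR-34a (5.16-fold) and miR-34a* (28.6-fold) were both called. miR-191* was called at 138-fold and miR-191 was not, at 1.62-fold. miR-28 was called at 5.17-fold and miR-28-3p was not, at 1.96-fold. miR-30a-5p was called and miR-30a-3p was not, at 2.73-fold. miR-628-5p (0.638) and miR-628-3p (0.159) were not called, and both were called lower after centring. The pairs were taken by name after the values were seen, and the differences between strands were not tested.

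Some cells held short decimals (at most 6 places), where others held the long decimals of single-precision values. They made up 46.0% of the values of replicate b on card A (46 of 100), against 15.3% in a, 20.9% in c and 10.7 to 15.8% on card B. In replicate b the median distance of a value from the mean of the other 2 replicates was 0.70 log2 units for the 46 short-decimal values and 1.05 for the 51 others with complete data (permutation test with 100000 resamples, two-sided, p = 0.108). Of these, 45 and 42 lay above 1.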
